A study of Homo sapiens with 8 samples.

How the data were processed

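RNA of HepG2 cells was compared on 8 arrays with 2 colours each, in 3 groups: lipid-loaded cells (3 arrays), lipid-loaded cells given fenofibrate (3 arrays) and lipid-loaded cells given linalool (2 arrays). Per the labels' protocols, 8 µg of purified total RNA was reverse transcribed from oligo(dT) primers and the products were coupled to Cy3 or Cy5. On every array the untreated control carried Cy5 and the treated sample Cy3, with no dye swap. A gene-specific dye effect therefore stays in each ratio against the control. It cancels in differences between groups only where it is equally strong on every array. The trend of the ratio with spot brightness differed, with Spearman rho from 0.0326 to 0.375 over the arrays, and does not cancel. The labels call the arrays of a group biological replicates and do not say that they came from separate cultures. The p-values therefore measure only the spread between these samples, which may be technical. Each treated group was tested against a ratio of 0, which leaves out the control's own spread.

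The authors deposited a table of processed values for 29187 probes, with 4 missing values, and scanner output was not analysed here. The scanner, the background correction and the normalization are not given in the sources used here. The deposited values were taken as log2 ratios of the 2 channels, which was settled from the values themselves. On every array, 100% of the values equalled log2 of a ratio with 3 decimals plus 1 constant, within a tolerance of 0.0001, over ratios from 0.2 to 2. With the sign turned, at most 30.6% did. Scale and centring are thus known: base 2, with each column's mean within 5.9e-05 of 0. Which channel is the numerator stays unknown. The column medians were −0.0048, 0.0402 and 0.058 for lipid-loaded replicates 1, 2 and 3. They were 0.0865, 0.0635 and −0.012 for fenofibrate replicates 1, 2 and 3, and 0.0452 and 0.0507 for linalool replicates 1 and 2.

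For the direction, anchor genes known as responsive to oleate or to a PPARα agonist in liver cells were fixed, and 7 were used: PLIN2, PDK4, ANGPTL4, CPT1A, SLC25A20, ACADVL and CREB3L3. A direction was to be called likely only if at least 3 in 4 of the measured anchors shared a sign both in the fenofibrate mean and in the difference fenofibrate minus lipid-loaded. All values were kept with their deposited sign.

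Gene symbols came from the platform annotation supplied with the values: 25053 probes had 1 symbol, 0 had several and 4134 had none. Of these, 24981 were matched by gene identifier to a current human gene table, and 0 symbols changed. Genomic coordinates were not used here. Probes of a gene were averaged on the log2 scale, giving 18821 genes, of which 18819 had at least 2 values in every group and were tested. Probes without a symbol were left out of the gene tests. Probes of a gene disagreed in sign, each past an unadjusted p of 0.05, for 152 genes in lipid-loaded against untreated cells and for 8 to 36 genes in the other comparisons.

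Each comparison was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with the data.table package (version 1.17.8) for reading the values. A single fit to all 8 arrays held 1 coefficient per group, so that the groups shared an estimate of the spread and the 2 linalool arrays could be tested. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are those of the fit. Gene lists were tested with limma's camera, with a preset correlation of 0.01 between genes, adjusted over 180 tests (29 lists and the anchors in 6 comparisons). Camera with an estimated correlation and limma's fry were run beside it. With the few residual degrees of freedom here, a call lost with an estimated correlation does not decide against a list. The estimates were 0.295 for cell cycle, 0.315 for oxidative phosphorylation, 0.243 for ribosomal and 0.399 for proteasome genes, and −0.037 for bile acid genes. Where the genes of a list do vary together more than the preset 0.01 assumes, the camera p-values with the preset are too small. Members of a list were counted over all genes tested and adjusted over the list alone. The groups, comparisons, tests, lists, anchors, rule for named genes and most alternatives were chosen before the data were examined.

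The 29 lists covered lipid metabolism (PPARα targets, fatty acid and triglyceride synthesis, cholesterol synthesis, LXR targets, lipid droplets, apolipoproteins, bile acid genes, PPAR and partner receptors), stress programmes (unfolded protein response, NRF2, heat shock, metallothioneins, p53, immediate early genes, interferon, acute phase), and liver functions (hepatocyte proteins, xenobiotic metabolism, urea cycle, complement and coagulation, gluconeogenesis). Further lists held glycolysis and hypoxia, cell cycle, oxidative phosphorylation, ribosomal proteins, proteasome and lysosome genes. Markers of other cell types and olfactory receptor genes completed the set. Genes were named by 3 rules. The first took, per comparison, up to 8 genes each way with the largest change among those called and of the same sign on every array. Where no gene was called, it took the 4 with the smallest p each way, given as values. The second took up to 4 members with the smallest p from each list that passed camera and from the PPARα, fatty acid synthesis, cholesterol synthesis, lipid droplet and xenobiotic lists. The last took genes named in advance, where measured: PPARA, PLIN2, PDK4, CPT1A, ANGPTL4, FASN, SCD, SREBF1 and CYP1A1.

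A stand-in for spot brightness was derived with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, since intensities were not analysed here. A dim spot has small whole-number intensities, so its 3-decimal ratio is more often a quotient of small whole numbers. The smallest sum of numerator and denominator (each under 400) that gives the ratio, on the log2 scale and less its mean over ratios within 50 grid steps, was averaged over the other 7 arrays. It is a noisy measure, and removing its trend takes out only part of the trend with brightness. Figures were drawn with matplotlib 3.10.9.

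The steps were tested on simulated data for 18819 genes, with 200 changed genes at the real spread. Of genes changed by log2 0.5, 1 and 2, limma recovered 4.48%, 77.6% and 98.5% in lipid-loaded against untreated cells. It recovered 4.48%, 64.2% and 100% in the fenofibrate group against untreated, and 1.49%, 35.8% and 100% in the linalool group against untreated. For fenofibrate against lipid-loaded the shares were 1.49%, 13.4% and 98.5%. For linalool against lipid-loaded they were 0%, 10.4% and 93.9%, and for linalool against fenofibrate 1.49%, 10.4% and 92.4%. Between 2 and 9 unchanged genes were called per comparison. The simulated noise was independent between genes, and 200 genes changed, against 6555 called in lipid-loaded against untreated cells. The adjusted threshold depends on the share changed, so the recovered shares do not carry over to that comparison.

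The alternatives were each array's median subtracted, quantile normalization, arrays scaled to the same spread, and complete genes or complete probes only. Estimated array weights, robust eBayes, the comparison's own arrays only, a replicate block, single probes, a minimum of 1.5-fold and each array left out were also run. A lone linalool array left after leaving out the other was assumed to vary like the other groups. Removing the trend with brightness (loess, span 0.3) and keeping only the brighter 50% of the probes were chosen after seeing the data. The comparisons with lipid-loaded cells share those arrays, so unchanged groups were simulated against them 100 times.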

Results

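Gene expression was measured in HepG2, an established human hepatoblastoma cell line used as a model of hepatocytes, to compare how linalool and fenofibrate act on lipid-loaded cells. Linalool is a fragrant monoterpene alcohol of many plant oils, and fenofibrate is a lipid-lowering drug whose active acid binds the nuclear receptor PPARα. Per the labels' protocols, cells were loaded for 24 h with 400 µM oleate on albumin at a ratio of 6.6. Another label names oleate and palmitate together, and the sources used here do not settle which was given. Loaded cells were then washed and kept for 24 h in serum-free medium without a compound, with 100 µM fenofibrate or with 1 mM linalool. The labels do not say whether the untreated cells also spent this time without serum. Each of the 8 arrays set 1 treated sample against untreated cells: 3 arrays for lipid-loaded cells, 3 for fenofibrate and 2 for linalool, and this number limits the precision.

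Ratios are given as deposited, on the log2 scale. The labels do not state which channel is the numerator, and the anchor genes did not settle it. Of 7 measured anchors, 6 had a positive mean log2 ratio with fenofibrate, but 4 were positive in the difference fenofibrate minus lipid-loaded, where 6 were needed. Positive and negative therefore name the deposited sign, and no gene is said to be higher or lower in treated than in untreated cells. In differences between groups, negative means a lower deposited ratio in the first group named. The median SE of a gene was 0.193 for a group of 3 arrays and 0.236 for the 2 linalool arrays. Fenofibrate replicate 3 stood apart from the other 7 arrays. Across genes, it correlated with the mean of the others at r = 0.127, against 0.440 to 0.716 for the other arrays. Genes are not independent replicates.

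In lipid-loaded against untreated cells, 31 of 39 PPARα targets and oxidation genes and 9 of 18 lipid droplet genes had positive log2 ratios. PLIN2, the coat protein of hepatocyte lipid droplets, stood at 0.95 (SE 0.17, n = 3, limma adjusted p = 0.0135). PLIN3, another droplet coat protein, stood at 0.82 (SE 0.16), CIDEC, a droplet fusion protein, at 0.66 (SE 0.16), and FITM2, which takes part in droplet formation, at 0.75 (SE 0.22). Among PPARα targets, CREB3L3, a liver transcription factor of triglyceride metabolism, was at 0.89 (SE 0.16), HSD17B4 of peroxisomal oxidation at 0.81 (SE 0.16) and ETFB of mitochondrial electron transfer at 0.84 (SE 0.15). All of these passed the test, with adjusted p from 0.0135 to 0.0263. CPT1A, the gate of mitochondrial fatty acid oxidation, was at 0.37 (SE 0.17, adjusted p = 0.103) and PPARA itself at 0.33 (SE 0.16, adjusted p = 0.129). PDK4 at −0.27 (SE 0.23, adjusted p = 0.356) and ANGPTL4 at −0.25 (SE 0.17, adjusted p = 0.261), both fatty acid responsive PPAR targets, also did not pass.

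Over all genes tested, 6555 of 18819 changed in this comparison, 4537 with a positive and 2018 with a negative ratio. Counts of list members are to be read against these shares. Of 39 measured PPARα targets and oxidation genes, 25 changed, all with a positive ratio, and 25 did so adjusted over the list alone. The list mean was 0.46 (camera adjusted p = 6.0e-05, and adjusted p = 0.347 with an estimated correlation). None of the 73 list calls made over the 6 comparisons held with an estimated correlation, and 29 of them were lost with fry. The smallest adjusted p with an estimated correlation was 0.347 in every comparison. Whether that setting could recover a list was not simulated, so a loss there does not decide whether a list differs. The lipid droplet list of 18 genes did not stand apart (mean 0.12, adjusted p = 0.719). Of its members 5 changed, or 7 with a positive and 2 with a negative ratio adjusted over the list alone. Among the 22 genes of fatty acid and triglyceride synthesis, 11 changed with a positive and 1 with a negative ratio, and 12 and 2 adjusted over the list alone. Its mean was 0.31 (adjusted p = 0.0187, and adjusted p = 0.497 with an estimated correlation), and the call was lost with the brightness trend removed (adjusted p = 0.0918). PGD of the pentose phosphate pathway at 0.76 (SE 0.15), the elongase ELOVL5 at 0.67 (SE 0.16), and MLXIPL, the carbohydrate response factor, at 0.67 (SE 0.16) passed. So did FASN, fatty acid synthase, at 0.52 (SE 0.18, adjusted p = 0.0423). The desaturase SCD at 0.48 (SE 0.17, adjusted p = 0.0524) and SREBF1, the regulator of lipid synthesis, at 0.24 (SE 0.18, adjusted p = 0.288) did not.

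Of 21 cholesterol synthesis genes, 6 changed and 10 did so adjusted over the list alone, all positive, with MSMO1 at 0.88 (SE 0.16) and FDPS at 0.57 (SE 0.17). The list mean was 0.41 (camera adjusted p = 0.00509, and adjusted p = 0.347 with an estimated correlation). Apolipoproteins and lipoprotein genes had 11 positive and 1 negative call among 19 (mean 0.37, adjusted p = 0.0140, and adjusted p = 0.347 with an estimated correlation), and 12 and 1 adjusted over the list alone. APOA1, the main protein of high-density lipoprotein, was at 0.99 (SE 0.15), APOA2 at 0.82 (SE 0.16), and LPL, lipoprotein lipase, at −0.96 (SE 0.20). Secreted hepatocyte proteins had 17 calls of 24, or 19 adjusted over the list alone, all positive, such as AFP, the fetal serum protein, at 0.93 (SE 0.19) (mean 0.55, adjusted p = 5.8e-05, and adjusted p = 0.347 with an estimated correlation). In the xenobiotic list of 24 genes, 9 positive and 1 negative call, or 9 and 2 adjusted over the list alone, did not make the list stand apart (adjusted p = 0.415). Its member CYP1A2, a drug and caffeine oxidase, was at 1.23 (SE 0.17), while CYP1A1 was at −0.05 (SE 0.26, adjusted p = 0.888).

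Housekeeping and growth genes had positive ratios as groups in the lipid-loaded cells. Of 36 cell cycle genes, 30 changed and 32 did so adjusted over the list alone, all positive (mean 0.65, camera adjusted p = 1.7e-08), with PCNA, the replication clamp, at 0.95 (SE 0.17), TYMS at 0.90 (SE 0.17) and MCM7 of the replicative helicase at 0.83 (SE 0.15). Of 27 proteasome genes 26 changed, and 26 adjusted over the list alone (mean 0.73, adjusted p = 3.9e-09). Ribosomal proteins had 38 positive and 1 negative call among 48, the same counts adjusted over the list alone (mean 0.60, adjusted p = 6.0e-09), with RPS25 at 1.03 (SE 0.17). Each of these 3 calls was lost with an estimated correlation, at adjusted p = 0.347. Oxidative phosphorylation genes had 33 positive calls and 1 negative call among 41, or 33 and 3 adjusted over the list alone (mean 0.54, adjusted p = 1.5e-06, and adjusted p = 0.434 with an estimated correlation). Glycolysis and hypoxia genes had 14 positive calls and 1 negative call among 26, or 18 and 1 adjusted over the list alone (mean 0.49, adjusted p = 1.6e-04, and adjusted p = 0.347 with an estimated correlation), with the glycolytic enzyme ENO1 at 0.95 (SE 0.16).

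Several lists of stress genes also had positive means. The unfolded protein and integrated stress response list had 21 calls among 32 and 22 adjusted over the list alone, all positive (mean 0.57, adjusted p = 1.2e-05, and adjusted p = 0.347 with an estimated correlation). CALR, a chaperone of the endoplasmic reticulum, was at 1.11 (SE 0.20), MTHFD2 at 1.03 (SE 0.18) and ASNS, asparagine synthetase, at 1.18 (SE 0.24). NRF2 targets had 14 positive calls and 1 negative call among 22, the same adjusted over the list alone (mean 0.49, adjusted p = 3.3e-04, and adjusted p = 0.386 with an estimated correlation), with FTL, the ferritin light chain, at 0.98 (SE 0.16). Heat shock genes (mean 0.42, adjusted p = 0.0113, and adjusted p = 0.386 with an estimated correlation) had 11 positive calls and 1 negative call among 18, also adjusted over the list alone. Lysosome genes (mean 0.45, adjusted p = 3.6e-04) had 18 and 1 among 25, or 19 and 1 adjusted over the list alone, and p53 targets (mean 0.45, adjusted p = 0.0102) had 6 and 0 among 17, also adjusted over the list alone. Both calls were lost with an estimated correlation, at adjusted p = 0.347. Complement and coagulation genes had 11 positive and 1 negative call among 26, or 11 and 2 adjusted over the list alone. Their mean was 0.31 (adjusted p = 0.0384, and adjusted p = 0.577 with an estimated correlation), and the call was lost without lipid-loaded replicate 2 (adjusted p = 0.109), with quantile normalization, with the arrays scaled to the same spread and with the brightness trend removed (adjusted p = 0.0865).

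Olfactory receptors and markers of other cell types had negative means. Of 296 olfactory receptor genes, 46 changed with a negative and 15 with a positive ratio, or 20 and 14 adjusted over the list alone (mean −0.29, adjusted p = 4.0e-07). Markers of stromal, endothelial and blood cells had 7 negative calls and 1 positive call among 20, or 8 and 2 adjusted over the list alone (mean −0.30, adjusted p = 0.0187), with the endothelial cadherin CDH5 at −1.11 (SE 0.23) and the collagen COL1A1 at −1.02 (SE 0.25). Both calls were lost with an estimated correlation, at adjusted p = 0.347. The ratio also went with spot brightness, with Spearman rho across probes of 0.375, 0.324 and 0.339 on lipid-loaded replicates 1, 2 and 3. The median brightness percentile was 76.1 for ribosomal proteins, 71.5 for the proteasome and 67.7 for cell cycle genes, against 31.0 for olfactory receptors and 34.4 for markers of other cell types. With only the brighter probes kept, the calls of fatty acid synthesis, cholesterol synthesis, apolipoproteins, heat shock, p53 targets, complement genes and these markers were lost.

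**Figure D1:**
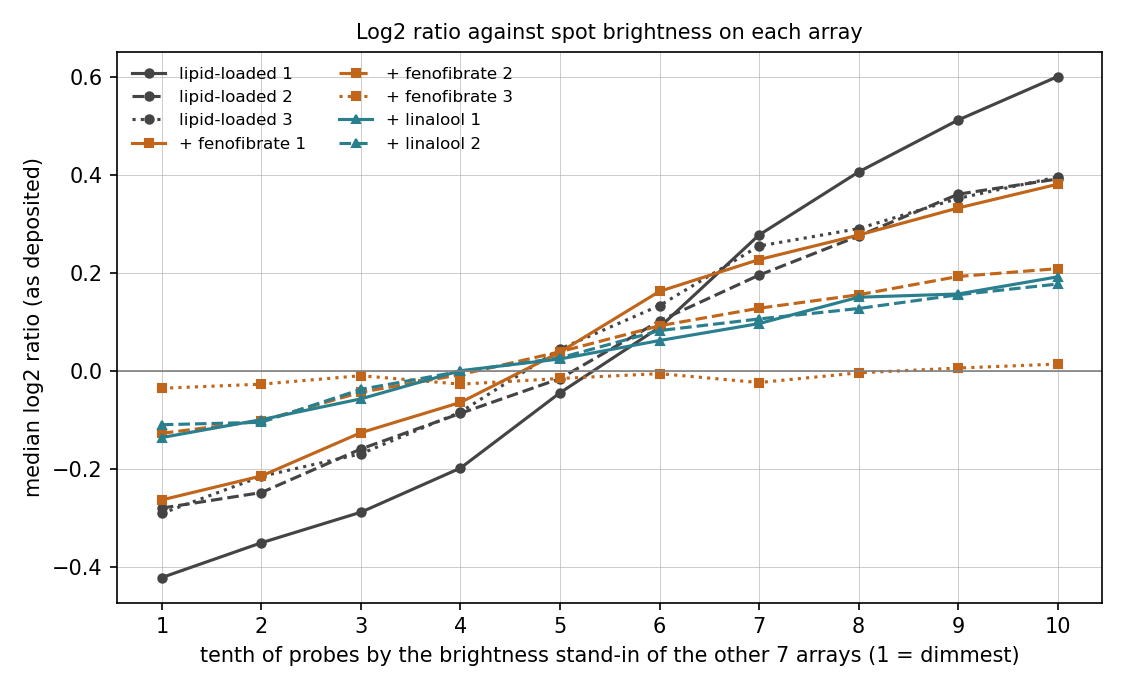
Median deposited log2 ratio (vertical axis) of the probes in 10 equal groups by the brightness stand-in of the other 7 arrays (horizontal axis, 1 = dimmest), with 1 line for each of the 8 arrays. On lipid-loaded replicate 1 the median went from −0.42 in the dimmest to 0.60 in the brightest group, and on fenofibrate replicate 3 from −0.04 to 0.01.

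Over all genes, 6555 of 18819 changed in lipid-loaded against untreated cells, 4537 with a positive and 2018 with a negative ratio (limma, n = 3). The largest positive ratio was that of RCN2, a calcium-binding protein of the endoplasmic reticulum, at 3.06 (SE 0.30, adjusted p = 0.00809). Its 2 probes differed widely in size, 5.33 to 5.49 against 0.57 to 0.90 over the 3 arrays. BAX, a promoter of apoptosis, was at 1.32 (SE 0.19), FKBP10, a collagen-folding protein, at 1.33 (SE 0.33), and SEPTIN9, a cytoskeletal septin, at 1.23 (SE 0.20). Among negative ratios were POU3F3, a transcription factor of neural cells, at −2.31 (SE 0.29), the zinc finger factor OVOL3 at −1.74 (SE 0.28) and ADIPOQ, which codes for the adipocyte hormone adiponectin, at −1.87 (SE 0.33). The count rested on the arrays and their scaling: it was 0 with the arrays scaled to the same spread (smallest adjusted p 0.0545) and 0 without lipid-loaded replicate 1 (0.0987). It was 2010 without replicate 2, 3087 without replicate 3, 2877 (2235 positive, 642 negative) with quantile normalization and 3816 with the brightness trend removed, of which 3460 were among the 6555.

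In the fenofibrate group against untreated cells, 29 of 39 PPARα targets and 8 of 18 lipid droplet genes had positive ratios, but no gene passed the test. CREB3L3 stood at 1.20 (SE 0.16, n = 3, limma adjusted p = 0.0968), FASN at 0.96 (SE 0.18), ECI1, an isomerase of fatty acid oxidation, at 0.91 (SE 0.20), and FABP1, the liver fatty acid binding protein, at 0.89 (SE 0.19). PLIN2 was at 0.77 (SE 0.17), ACADVL, an acyl-CoA dehydrogenase, at 0.76 (SE 0.16), CPT1A at 0.40 (SE 0.17) and ANGPTL4 at 0.44 (SE 0.17), while PDK4 was at −0.66 (SE 0.23). FASN, ECI1, FABP1, PLIN2 and ACADVL each had adjusted p = 0.132. Of 39 PPARα targets, 0 changed over all genes, and 12 with a positive and 1 with a negative ratio adjusted over the list alone. The list mean was 0.28 (camera adjusted p = 3.4e-05, and adjusted p = 0.347 with an estimated correlation), and without the anchor genes it was 0.24 (adjusted p = 0.00107).

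Apolipoproteins had 6 positive calls adjusted over the list alone and 0 over all genes (mean 0.32, adjusted p = 2.9e-04, and adjusted p = 0.347 with an estimated correlation), with APOA2 at 0.85 (SE 0.16) and APOA1 at 0.70 (SE 0.15). LXR targets, genes of cholesterol efflux and lipoproteins, had 4 positive calls adjusted over the list alone, with APOE at 0.70 (SE 0.16) and the transporter ABCA1 at 0.55 (SE 0.17). The LXR list mean was 0.27 (adjusted p = 0.0119, and adjusted p = 0.347 with an estimated correlation), and the call was lost without fenofibrate replicate 1 or 2 (highest adjusted p 0.0608). Lists of fatty acid synthesis (mean 0.21, adjusted p = 0.0140), cholesterol synthesis (0.21, 0.0190) and PPAR and partner receptors (0.24, 0.0272) passed too, with 1, 0 and 0 members adjusted over the list alone. They were lost with an estimated correlation, at adjusted p = 0.492, 0.355 and 0.347, and without fenofibrate replicate 1, the receptor list also without replicate 3 or with array weights, with highest adjusted p 0.160, 0.0894 and 0.105 by leaving out an array. The lipid droplet list had a mean of 0.07, a median of −0.01 and adjusted p = 0.708, with 3 positive calls adjusted over the list alone. The xenobiotic list had a mean of 0.18 and adjusted p = 0.0515, again with 3 positive calls adjusted over the list alone, among them CYP1A2 at 1.00 (SE 0.17).

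Ribosomal proteins (mean 0.39, adjusted p = 4.1e-11) and the proteasome (0.40, 7.3e-09) had 32 and 16 positive calls adjusted over the list alone, the first also 3 negative ones. Hepatocyte proteins (0.34, 1.7e-05), NRF2 targets (0.32, 3.4e-05), glycolysis (0.29, 2.2e-04) and lysosome genes (0.25, 7.4e-04) had 10, 11, 11 and 1 positive calls adjusted over the list alone. NRF2 targets and glycolysis each also had 1 negative call. All 6 were lost with an estimated correlation, each at adjusted p = 0.347. Oxidative phosphorylation (0.29, 6.7e-06) and the unfolded protein response (0.25, 7.9e-04) had 13 and 2 positive calls adjusted over the list alone and were lost at adjusted p = 0.472 and 0.402. The cell cycle list (mean 0.20, adjusted p = 0.00385, and adjusted p = 0.568 with an estimated correlation) had 0 calls adjusted over the list alone and was lost without fenofibrate replicate 1 or 2 (highest adjusted p 0.125). Its median was 0.43 and 0.30 on replicates 1 and 2 and 0.00 on replicate 3. Olfactory receptors (−0.16, 2.5e-05) and markers of other cell types (−0.25, 0.00509) were negative, with 0 calls adjusted over the list alone, and were lost with an estimated correlation at adjusted p = 0.347. Marker genes were also lost without replicate 1 (adjusted p = 0.0644). With only the brighter probes kept, fatty acid synthesis, cholesterol synthesis, cell cycle, receptor and marker lists were lost.

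Over all genes, limma called 0 in the fenofibrate group, with 3410 at an unadjusted p under 0.05, where chance alone would give 941. That expectation, here and in the comparisons below, leaves out dye effects and the brightness trend, which can stay in the values. An excess over it is thus not by itself an effect of treatment. RCN2 was at 2.34 (SE 0.30, adjusted p = 0.0968), and at −0.07 with only the brighter probes kept. BRD3OS, an antisense transcript, was at 1.26 (SE 0.20, 0.132) and GATA1, an erythroid transcription factor, at −1.98 (SE 0.28, 0.0995). EWSAT1, a long non-coding RNA, was at −1.49 (SE 0.22, 0.0995) and TRIM35 at −1.68 (SE 0.27, 0.132). RCN2 was called with estimated array weights and without fenofibrate replicate 3 (1 gene each), and single probes called 3 genes.

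In the linalool group against untreated cells, 17 of 22 NRF2 and oxidative stress genes, 26 of 32 unfolded protein and integrated stress response genes and 6 of 7 metallothioneins had positive ratios, although no gene passed the test. MT2A, a zinc-binding metallothionein, stood at 1.75 (SE 0.25, n = 2, limma adjusted p = 0.0643), TIMP1, a metalloproteinase inhibitor, at 1.66 (SE 0.21, adjusted p = 0.0643), and S100P, a calcium-binding protein, at 1.67 (SE 0.24, adjusted p = 0.0643). ASNS was at 1.73 (SE 0.30, adjusted p = 0.125) and SLC7A11, the cystine transporter, at 1.32 (SE 0.20, adjusted p = 0.0961). The NRF2 targets ABCC2, an export pump, SRXN1, OSGIN1 and FTL were at 1.09 (SE 0.19), 1.02 (SE 0.21), 1.02 (SE 0.22) and 0.98 (SE 0.20). CYP1A2 was at 1.15 (SE 0.21, adjusted p = 0.128) and CYP1A1 at 1.03 (SE 0.32, adjusted p = 0.313). Of 22 NRF2 genes, 10 with a positive and 1 with a negative ratio changed adjusted over the list alone, and 0 over all genes (mean 0.43, camera adjusted p = 2.4e-06, and adjusted p = 0.347 with an estimated correlation).

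The unfolded protein and integrated stress response list had 8 positive calls adjusted over the list alone (mean 0.39, adjusted p = 3.4e-05), and the 7 measured metallothionein genes had 3 (mean 0.72, adjusted p = 5.9e-04). The lysosome list had 7 (mean 0.33, adjusted p = 1.1e-04), among them WIPI1 of autophagosome formation at 0.97 (SE 0.21). These 3 calls were lost with an estimated correlation, each at adjusted p = 0.347. Immediate early genes had a mean of 0.35 (adjusted p = 0.00136, and adjusted p = 0.386 with an estimated correlation) and 0 calls adjusted over the list alone, with EGR1 at 1.35 (SE 0.36). Without linalool replicate 2 this call was lost (adjusted p = 0.0761). Urea cycle and amino acid genes (0.27, adjusted p = 0.0290) and hepatocyte proteins (0.24, adjusted p = 0.0105) had 2 and 0 calls adjusted over the list alone. They were lost with an estimated correlation at adjusted p = 0.485 and 0.492, and without linalool replicate 1 at 0.157 and 0.428, and both also with only the brighter probes kept. Ribosomal proteins (0.34, 7.3e-09), the proteasome (0.42, 3.2e-08) and oxidative phosphorylation (0.26, 1.3e-04) were positive and olfactory receptors (−0.16, 1.3e-04) negative. Adjusted over the list alone they had 0 calls, except for 2 negative ones in oxidative phosphorylation. With an estimated correlation these 4 were lost at adjusted p = 0.347, 0.355, 0.498 and 0.347.

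The lipid lists did not pass with linalool. PPARα targets had a mean of 0.13 (adjusted p = 0.0944) and 0 calls adjusted over the list alone. The mean was 0.05 (adjusted p = 0.728) without linalool replicate 1 and 0.22 (adjusted p = 0.0227) without linalool replicate 2, where the list passed. Among its genes were PLIN2 at −0.17 (SE 0.21) and CPT1A at 0.32 (SE 0.21). Fatty acid synthesis (0.07, adjusted p = 0.434), cholesterol synthesis (0.03, 0.848), lipid droplet (mean 0.03, median −0.09, 0.941) and xenobiotic genes (0.14, 0.271) did not pass. Adjusted over the list alone, MVK, mevalonate kinase, at −1.24 (SE 0.22) was the call among cholesterol genes, CIDEC at 0.94 (SE 0.20) among droplet genes, and 5 xenobiotic genes passed. Over all genes limma called 0, with 2326 at an unadjusted p under 0.05 against 941 by chance. GUCY1B1, a guanylate cyclase subunit, was at −1.48 (SE 0.21) and the sodium channel SCN8A at −1.31 (SE 0.19), both at adjusted p = 0.0643, and RCN2 at 2.68 (SE 0.36). The count was 126 with the arrays scaled to the same spread and 99 with estimated array weights. It was 6 without fenofibrate replicate 3, 4 without linalool replicate 1, 2 without linalool replicate 2 and 1 with single probes.

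The remaining lists did not pass against untreated cells. In lipid-loaded cells these were LXR targets (adjusted p = 0.151), bile acid genes (0.422), metallothioneins (0.305), acute phase genes (mean 0.01, median −0.12, test negative, 0.882), interferon genes (0.434), gluconeogenesis and FOXO targets (0.682), immediate early genes (0.495), urea cycle genes (0.129) and PPAR and partner receptors (0.173).

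**Figure D2:**
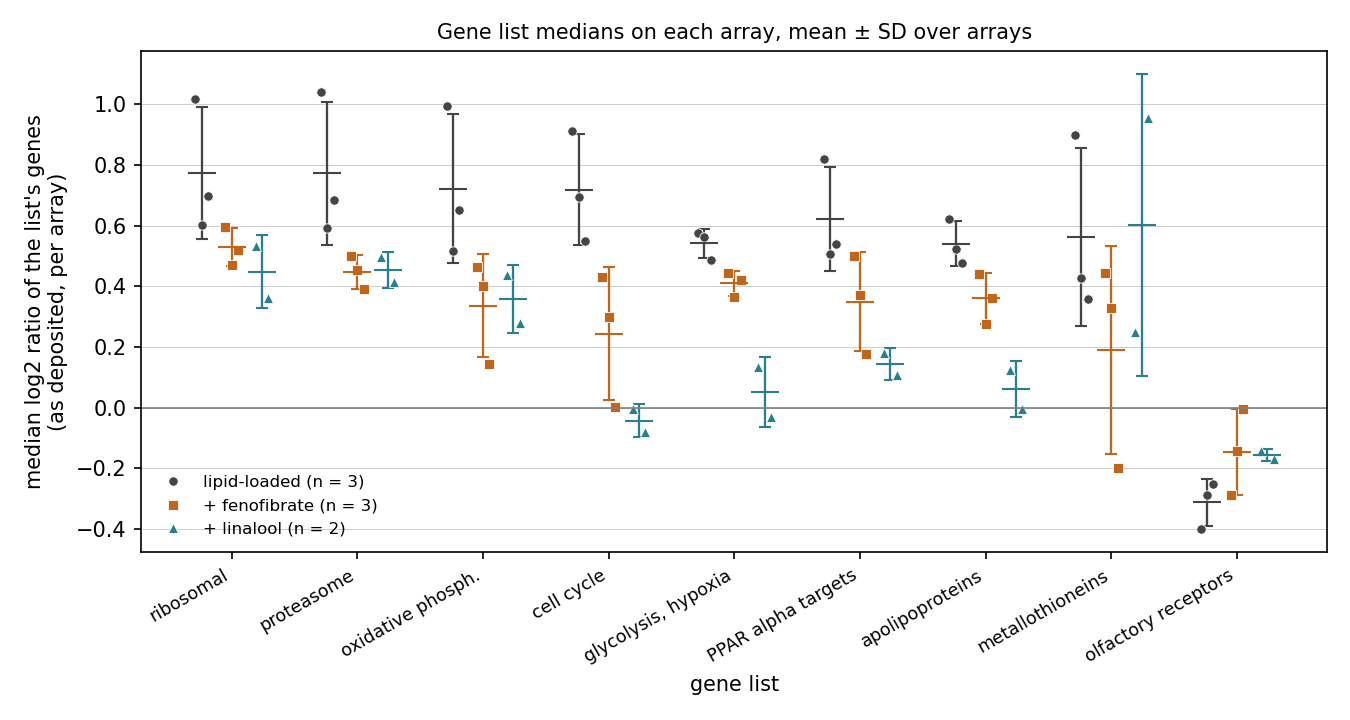
Median deposited log2 ratio of the genes of 9 lists (vertical axis) on each of the 8 arrays (points), by list (horizontal axis) and group, with bars at the mean ± SD over the arrays of a group. The cell cycle medians lay between 0.55 and 0.91 on the lipid-loaded arrays, between 0.00 and 0.43 with fenofibrate and at −0.00 and −0.08 with linalool.

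Fenofibrate was then compared with lipid-loaded cells, which had the same loading and no compound. Array differences such as the brightness trend do not cancel in this comparison, so it does not isolate the drug. Cell cycle genes had the lower ratio with fenofibrate: 34 of 36 were negative in the difference, with a mean of −0.45 (camera adjusted p = 1.1e-07, and adjusted p = 0.355 with an estimated correlation). With fry the call was lost (adjusted p = 0.0560). BUB1, a mitotic checkpoint kinase, was at −0.84 (SE 0.27, n = 3 against 3) and RRM1 of nucleotide synthesis at −0.90 (SE 0.34), and 0 members passed, also adjusted over the list alone. Without fenofibrate replicate 3 the list mean was −0.33 (adjusted p = 4.8e-06). Set against ribosomal and proteasome genes, the cell cycle mean was −0.10, −0.08 and −0.42 on fenofibrate replicates 1, 2 and 3, and −0.02, 0.15 and −0.12 on the lipid-loaded arrays. It thus lay outside the lipid-loaded range on replicate 3 alone, the array that stood apart. The p53 list was lower as well (mean −0.39, adjusted p = 0.00276, and adjusted p = 0.347 with an estimated correlation), with 2 calls adjusted over the list alone. BAX was at −1.43 (SE 0.27), TP53I3 at −0.86 (SE 0.24) and the death receptor TNFRSF10B at −0.81 (SE 0.27). The p53 call was lost with only the brighter probes kept.

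The PPARα list did not pass in this comparison (mean −0.18, adjusted p = 0.0742), and passed with a negative mean without the anchor genes (−0.22, adjusted p = 0.0222). Among its members, ANGPTL4 was at 0.68 (SE 0.24) and FGF21, a liver hormone, at 0.60 (SE 0.25), while TXNIP, an inhibitor of thioredoxin, was at −0.71 (SE 0.31). CPT1A was at 0.03 (SE 0.24), PLIN2 at −0.18 (SE 0.24), PDK4 at −0.39 (SE 0.33) and FASN at 0.45 (SE 0.25), all with adjusted p of 0.472 or above. Fatty acid synthesis (mean −0.11, adjusted p = 0.432), cholesterol synthesis (−0.20, 0.129), lipid droplet (−0.05, 0.882) and xenobiotic genes (0.04, 0.836) did not pass, with 0 members adjusted over the list alone.

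Lower ratios with fenofibrate were also found for the proteasome (mean −0.33, adjusted p = 1.4e-04), the unfolded protein response (−0.32, 0.00110), oxidative phosphorylation (−0.25, 0.00194), ribosomal proteins (−0.20, 0.0117) and complement genes (−0.24, 0.0443), and a higher one for olfactory receptors (0.14, 0.00224). Each had 0 members adjusted over the list alone. With an estimated correlation they were lost at adjusted p = 0.497, 0.422, 0.568, 0.598, 0.577 and 0.347. Oxidative phosphorylation was lost without lipid-loaded replicate 1, ribosomal proteins without that array or fenofibrate replicate 2, complement genes without lipid-loaded replicate 2 or fenofibrate replicate 3, and olfactory receptors without fenofibrate replicate 3, with highest adjusted p 0.0855, 0.117, 0.295 and 0.0980. Ribosomal and complement calls were also lost with the brightness trend removed (adjusted p = 0.0681 and 0.0904). With the arrays scaled to the same spread, all 6 of these calls were lost. Complement genes were lost in quantile normalization and with array weights, olfactory receptors in quantile normalization, and the unfolded protein response, complement genes and ribosomal proteins with only the brighter probes kept. The trend with brightness, from 0.324 to 0.375 as rho on the lipid-loaded arrays, was 0.330, 0.201 and 0.0326 on fenofibrate replicates 1, 2 and 3. Over all genes limma called 0, with 1934 at an unadjusted p under 0.05 against 941 by chance, and no alternative called any. Other divisions of the same 6 arrays into 3 and 3 gave up to 1574 at an unadjusted p under 0.05. Each of these divisions keeps part of the difference between the groups, so they do not show what arrays alone would give. HAUS7, a spindle protein, was at 1.54 (SE 0.26), LAIR1, a leukocyte receptor, at 1.39 (SE 0.24), and APOL1 at −1.08 (SE 0.26), each at adjusted p = 0.472.

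Linalool was compared with lipid-loaded cells in the same way, to ask what the terpenoid changed in loaded cells. Cell cycle genes again had the lower ratio: 35 of 36 were negative, with a mean of −0.71 (camera adjusted p = 2.5e-14, and adjusted p = 0.347 with an estimated correlation). Adjusted over the list alone, 18 passed, and 0 over all genes. MCM5 and MCM7 of the replicative helicase were at −1.13 (SE 0.28, n = 2 against 3) and −1.02 (SE 0.24), BIRC5, survivin, at −1.11 (SE 0.27) and PLK1, a mitotic kinase, at −1.04 (SE 0.29). Glycolysis and hypoxia genes had 11 negative calls and 1 positive call adjusted over the list alone (mean −0.52, adjusted p = 3.3e-06, and adjusted p = 0.347 with an estimated correlation). The glucose transporter SLC2A3 was at −1.36 (SE 0.33), PFKFB4, a regulator of glycolysis, at −1.18 (SE 0.28), the aldolase ALDOA at −1.04 (SE 0.29) and BNIP3, a hypoxia-responsive mitophagy receptor, at −0.90 (SE 0.28).

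PPARα targets, cholesterol synthesis genes and apolipoproteins had lower ratios with linalool as lists, while droplet genes went both ways. PLIN2 was at −1.11 (SE 0.27, adjusted p = 0.325), CREB3L3 at −0.91 (SE 0.25), FABP1 at −0.89 (SE 0.30) and the lipase PNPLA2 at −1.13 (SE 0.34), while the droplet protein PLIN4 was at 0.93 (SE 0.27). The PPARα list mean was −0.33 (adjusted p = 3.7e-04, and adjusted p = 0.358 with an estimated correlation), with 0 members adjusted over the list alone, and −0.32 without the anchor genes (adjusted p = 0.00159). Cholesterol synthesis was lower (mean −0.38, adjusted p = 0.00291, and adjusted p = 0.347 with an estimated correlation), with MVK at −1.48 (SE 0.29) as the call adjusted over the list alone and MVD of the same pathway at −1.04 (SE 0.31). Apolipoproteins had 5 negative calls adjusted over the list alone (mean −0.32, adjusted p = 0.0338, and adjusted p = 0.362 with an estimated correlation). APOC3, an inhibitor of triglyceride clearance, was at −1.35 (SE 0.29), APOA5, which promotes it, at −1.28 (SE 0.26), MTTP, needed to assemble lipoproteins, at −1.03 (SE 0.26) and APOA1 at −0.93 (SE 0.24). That call was lost without lipid-loaded replicate 1, fenofibrate replicate 3 or linalool replicate 2 (highest adjusted p 0.0745), with quantile normalization, the arrays scaled to the same spread, array weights, the comparison's own arrays or the brighter probes only, and with the brightness trend removed (adjusted p = 0.0619). Fatty acid synthesis did not pass (mean −0.24, adjusted p = 0.0543), with the desaturase FADS2 at −1.15 (SE 0.31) and FASN at −0.07 (SE 0.28), nor did the lipid droplet list (mean −0.09, median 0.12, test negative, adjusted p = 0.747) with 1 positive and 2 negative calls adjusted over the list alone. CPT1A was at −0.04 (SE 0.26).

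Hepatocyte proteins (mean −0.32, adjusted p = 0.00602), the proteasome (−0.31, 8.8e-04), oxidative phosphorylation (−0.28, 0.00107), ribosomal proteins (−0.26, 0.00224) and p53 targets (−0.33, 0.0371) were lower. Bile acid genes (0.29, 0.0323), markers of other cell types (0.22, 0.0405) and olfactory receptors (0.14, 0.00671) were higher. Adjusted over the list alone, 1 gene each passed among p53 targets, markers of other cell types (CD14 of monocytes) and oxidative phosphorylation (UQCRB, at 1.30, SE 0.30), and 0 in the others. With an estimated correlation these 8 were lost at adjusted p from 0.347 to 0.561. Hepatocyte and ribosomal proteins were lost without linalool replicate 2, and p53 targets without lipid-loaded replicate 2, fenofibrate replicate 3 or linalool replicate 1, with highest adjusted p 0.186, 0.106 and 0.157. Bile acid genes were lost without lipid-loaded replicate 3 or linalool replicate 1, and olfactory receptors without lipid-loaded replicate 1 or linalool replicate 1, with highest adjusted p 0.194 and 0.0630. Marker genes were lost without lipid-loaded replicate 1 or 2, fenofibrate replicate 3 or linalool replicate 2 (highest adjusted p 0.133). With the arrays scaled to the same spread, all but bile acid genes were lost, and with quantile normalization all but bile acid and oxidative phosphorylation genes. Bile acid genes, p53 targets and ribosomal proteins were lost with only the brighter probes kept, p53 targets and marker genes with array weights, and marker genes with the comparison's own arrays. With the brightness trend removed, p53 targets, marker genes and olfactory receptors were lost (adjusted p = 0.102, 0.0904 and 0.0619), and the trend was 0.199 and 0.194 as rho on the linalool arrays.

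Against lipid-loaded cells, NRF2 targets (mean −0.06, adjusted p = 0.900) and the unfolded protein response (−0.18, 0.134) did not pass. Xenobiotic genes did not pass as a list (mean −0.00, median 0.06, adjusted p = 0.977), with CYP1A1 at 1.08 (SE 0.42) and the sulfotransferase SULT2A1 at −0.92 (SE 0.24). Over all genes limma called 0 in linalool against lipid-loaded cells, with 2176 at an unadjusted p under 0.05 against 941 by chance. CYP24A1, the vitamin D hydroxylase, was at 1.95 (SE 0.32), the oxidase CYP2S1 at 1.87 (SE 0.32), UBD, a ubiquitin-like modifier, at −1.52 (SE 0.26) and DKK1, a Wnt inhibitor, at −1.48 (SE 0.26), each at adjusted p = 0.296. Without linalool replicate 1 the count was 1, and it stayed at 0 in the other settings.

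**Figure D3:**
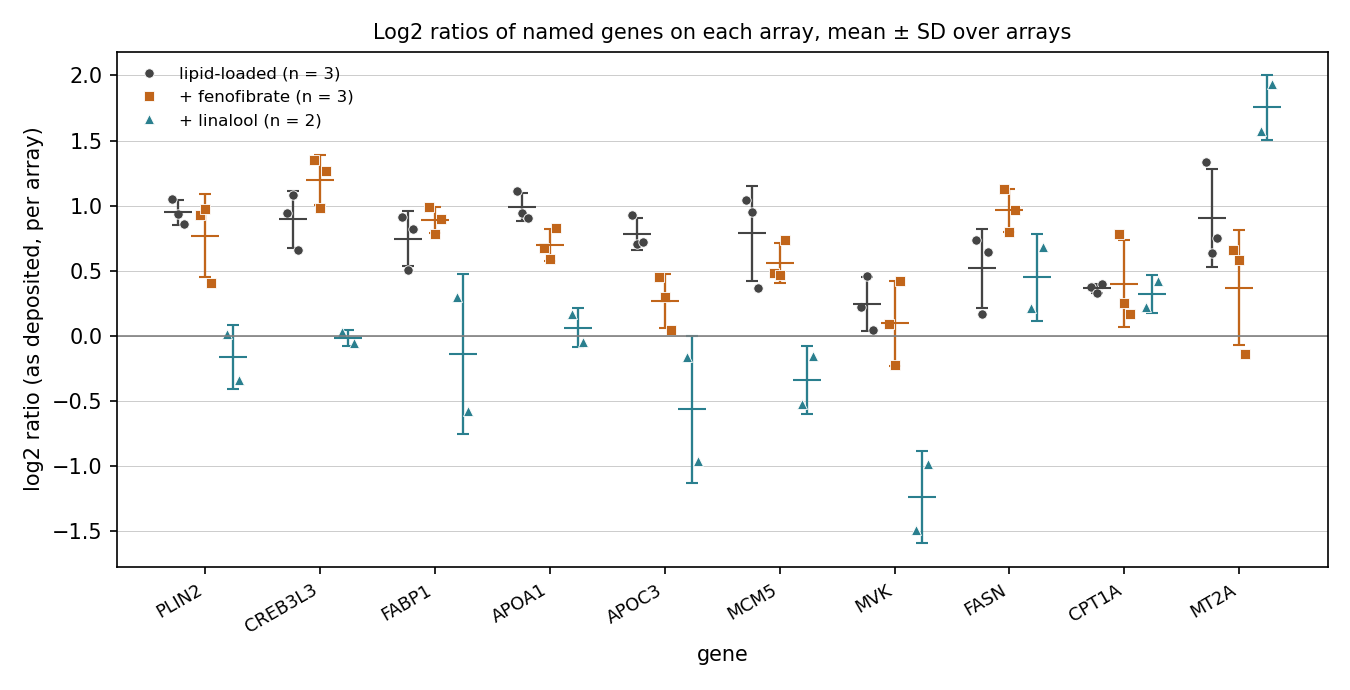
Deposited log2 ratio (vertical axis) of 10 named genes (horizontal axis) on each of the 8 arrays, with bars at the mean ± SD over the arrays of a group. PLIN2 had group means of 0.95 in lipid-loaded cells, 0.77 with fenofibrate and −0.17 with linalool, and MT2A of 0.91, 0.37 and 1.75.

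Linalool and fenofibrate, which are not structurally related and were given at different doses (1 mM and 100 µM), were compared directly. Cell cycle genes had a lower ratio with linalool than with fenofibrate (mean −0.26, camera adjusted p = 6.0e-05), 32 of 36 being negative, with MCM5 at −0.90 (SE 0.28, n = 2 against 3). Glycolysis and hypoxia genes were lower (mean −0.31, adjusted p = 5.3e-05), with the phosphofructokinase PFKL at −1.28 (SE 0.42) and PFKFB4 at −0.91 (SE 0.28). Apolipoproteins were lower (mean −0.27, adjusted p = 0.00318), with APOA5 at −0.89 (SE 0.26) and APOC3 at −0.83 (SE 0.29). Metallothioneins were higher (mean 0.57, adjusted p = 0.00345), with MT2A at 1.39 (SE 0.33), and MT2A and MT1B were calls adjusted over the list alone. The first 3 lists had 0 calls adjusted over the list alone. With fry the apolipoprotein call was kept (adjusted p = 0.0468) and the metallothionein call was lost (adjusted p = 0.119). With an estimated correlation the 4 calls were lost at adjusted p = 0.485, 0.347, 0.347 and 0.347, and the metallothionein call also without linalool replicate 2 (adjusted p = 0.133) and with only the brighter probes kept.

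PPARα targets had the lower ratio with linalool (mean −0.15, adjusted p = 0.0225, and adjusted p = 0.516 with an estimated correlation), with CREB3L3 at −1.22 (SE 0.25), as the call adjusted over the list alone, FABP1 at −1.03 (SE 0.30) and PLIN2 at −0.93 (SE 0.27). The call was lost without fenofibrate replicate 1 or linalool replicate 2 (highest adjusted p 0.411) with the arrays scaled to the same spread, and without the anchor genes (mean −0.09, adjusted p = 0.214). Immediate early genes were higher (mean 0.23, adjusted p = 0.0288, and adjusted p = 0.516 with an estimated correlation), with CCN1 at 0.94 (SE 0.31) and EGR1 at 1.29 (SE 0.46) and 0 calls adjusted over the list alone. That call was lost without fenofibrate replicate 2 or 3 or linalool replicate 2 (highest adjusted p 0.388), with array weights and with only the brighter probes kept (adjusted p = 0.0917). The median of these genes was −0.29 on fenofibrate replicate 3 and 0.43 and 0.21 on replicates 1 and 2. Fatty acid synthesis (mean −0.14, adjusted p = 0.129), cholesterol synthesis (−0.18, 0.0553), lipid droplet (−0.04, 0.759) and xenobiotic genes (−0.04, 0.733) did not pass. MVK at −1.33 (SE 0.29) was the call among cholesterol genes adjusted over the list alone, and FASN was at −0.52 (SE 0.28). Over all genes limma called 0, with 944 at an unadjusted p under 0.05, close to the 941 that chance would give. SH3RF1, a ubiquitin ligase, was at 1.84 (SE 0.31) and SCN8A at −1.36 (SE 0.24), both at adjusted p = 0.633. The count was 3 without linalool replicate 1 and 1 without linalool replicate 2.

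The differences of fenofibrate and of linalool from lipid-loaded cells correlated across genes at r = 0.640, and 76.4% of genes had the same sign. Unchanged groups simulated against the same lipid-loaded arrays gave r = 0.447 and 64.7%. The covariance was 0.116, against 0.0439 in the simulation. The 3 shared arrays could not be split with 2 on each side, so part of the excess may come from them.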

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

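All tests of explanations in this part were chosen after the results were seen.

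The test of the difference between the compounds set 6 lists apart between linalool and fenofibrate. The mean differences were −0.15 for PPARα targets (camera adjusted p = 0.0225), −0.27 for apolipoproteins (0.00318) and −0.31 for glycolysis and hypoxia genes (5.3e-05). They were −0.26 for cell cycle genes (6.0e-05), 0.57 for metallothioneins (0.00345) and 0.23 for immediate early genes (0.0288). No difference held with an estimated correlation, where the smallest adjusted p was 0.347, but that setting does not decide. With fry, 2 of 29 lists were called in this comparison, among them apolipoproteins (adjusted p = 0.0468). PPARα targets and metallothioneins were lost with fry (adjusted p = 0.274 and 0.119). Most of the 6 differences thus depend on the test used.

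Genes abundant in hepatocytes had positive and olfactory receptors negative ratios on the lipid-loaded arrays. A trend with spot brightness may account for part of this, since the ratio correlated with the brightness stand-in of the other arrays at rho = 0.324 or more on each lipid-loaded array. After each recovered ratio was moved at random within its near grid steps, rho was at most 0.0074 in size. On every array 100% of the values lay on the grid of a raw ratio plus 1 constant, which is consistent with no correction that depends on intensity. The share due to brightness and the share due to biology were not separated, and 3816 genes were called with the trend removed.

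Fenofibrate replicate 3 stood apart from the other 7 arrays. Poor spot measurement may be the reason: the 2 probes of a gene correlated at r = 0.0224 on this array (95% interval −0.0063 to 0.0511, 4667 genes), against 0.129 to 0.457 on the others. The brightness stand-in correlated with the other arrays at a mean rho of 0.0029 (SE of a pair 0.0059), against 0.0257 to 0.0686 for pairs among the others. This argues against a mislabelled sample of the same cells with spots of the usual quality and intensity scale. The stand-in depends on that scale, which may differ here: the median smallest sum was 76 on this array and 63 to 72 on the others. Mislabelling as such was thus not excluded. A mislabelled sample on a poorly measured array was not tested and stays open. Over 651 list genes the array correlated with the mean of the others at 0.332, with a positive sign (95% interval 0.262 to 0.399). This does not exclude turned dyes, since a gene-specific dye effect would keep its sign with the dyes turned.

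Cell cycle genes had a lower ratio with linalool than in lipid-loaded cells. The values argue against the brightness trend alone. Cell cycle genes less ribosomal and proteasome genes, brighter by the stand-in, still differed by −0.43 (means 0.00 and −0.43, SD between arrays of a group 0.153). The trend was not excluded, since the stand-in is noisy and ribosomal and proteasome genes differed as well (list means −0.26 and −0.31). A lone array was excluded, since the list mean stayed at −0.64 or further from 0 with any array left out. Shared variation of these genes between arrays could not be told apart, at adjusted p = 0.347 with an estimated correlation.

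For fenofibrate against lipid-loaded cells, the 6 arrays were also divided in all 10 ways into 3 and 3. The cell cycle mean of −0.45 was the largest of the 10 (1 of 10), with 0.363 as the highest size among the others. The count of changed genes was 0 in 10 of 10 divisions. Divisions numbering 10 are too few for a share under 0.05.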

How the results depend on the processing

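The brightness trend removal and the use of the brighter probes only were chosen after the result was seen, and the cause of the shifts below was not tested. The count in lipid-loaded against untreated cells was 6555. It was 2877 with quantile normalization (2235 positive and 642 negative, against 4537 and 2018), 0 with the arrays scaled to the same spread and 3816 with the brightness trend removed. It ranged from 0 to 7772 with 1 array left out: 0 without lipid-loaded replicate 1, 2010 without replicate 2, 3087 without replicate 3 and 7772 without fenofibrate replicate 3. Other settings gave 4902 (at least 1.5-fold) to 7404 (own arrays only).

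In the fenofibrate group against untreated cells the count of 0 became 1 with array weights and 3 with single probes (RCN2, RPH3A and RORA), and ranged from 0 to 1 with 1 array left out, RCN2 being called without fenofibrate replicate 3. In the linalool group against untreated cells it became 126 with the arrays scaled to the same spread, 99 with array weights and 1 with single probes (RCN2). With 1 array left out it ranged from 0 to 6: 6 without fenofibrate replicate 3, 4 without linalool replicate 1 (DNAAF8, GCG, ZNF892 and CCR8) and 2 without linalool replicate 2 (GPR171 and NOSTRIN). In linalool against lipid-loaded cells the range was 0 to 1 (CCR8, without linalool replicate 1). In linalool against fenofibrate it was 0 to 3 (DNAAF8, ZNF892 and CCR8, without linalool replicate 1), with 1 without linalool replicate 2 (NOSTRIN). Fenofibrate against lipid-loaded cells stayed at 0. These genes were chosen after their values were seen, and a lone linalool array was assumed to vary like the other groups.

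Arrays with the same replicate number did not pair clearly: their deviations from the group means correlated at −0.02 to 0.140 (1 of 7 pairs over 0.1), against −0.14 to 0.0664 with different numbers. The highest values, 0.140 and 0.0826, both came from lipid-loaded and fenofibrate arrays of the same number, so partial pairing was not excluded. A replicate block gave 6784 genes in lipid-loaded against untreated cells and 0 in the other comparisons. It did not keep 5 list calls: urea cycle genes for linalool against untreated cells (adjusted p = 0.0630), apolipoproteins (0.0716), p53 targets (0.051) and marker genes (0.0514) for linalool against lipid-loaded cells, and immediate early genes for linalool against fenofibrate (0.187).

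Of the 73 list calls, those kept with each array left out and in every other setting numbered 11 of 18 in lipid-loaded against untreated cells, 11 of 17 for fenofibrate and 8 of 11 for linalool against untreated cells. They were 1 of 8 (cell cycle) for fenofibrate and 4 of 13 for linalool against lipid-loaded cells, and 3 of 6 for linalool against fenofibrate. These counts leave aside fry and the estimated correlation. With fry the cell cycle call for fenofibrate against lipid-loaded cells was lost (adjusted p = 0.0560). No named gene or list turned its sign in a setting where it passed there or in the main test. Some that passed in neither turned, such as CYP1A1 in lipid-loaded against untreated cells (−0.05, and 0.24 without lipid-loaded replicate 2). PLIN2 in fenofibrate against lipid-loaded cells was at −0.18, and at 0.09 with the arrays scaled to the same spread.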

Other observations

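The comparisons in this part were chosen after the result was seen.

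The 2 probes of RCN2 differed in size but not in sign on the lipid-loaded arrays, and on fenofibrate replicate 3 they stood at 3.12 and −0.92. On fenofibrate replicates 1 and 2 and on both linalool arrays, 1 probe stood at 4.87 to 5.59 and the other at 0.33 to 0.39. The gene mean of RCN2 thus rests mainly on 1 probe in every group. The 2 probes of CPT1A gave 0.03 to 0.18 and 0.58 to 0.71 on the lipid-loaded arrays, so the gene mean of 0.37 averages unlike values. No named gene had probes of opposite sign that each had an unadjusted p under 0.05.

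Some lists that did not pass had a mean and a median of opposite sign. With linalool against lipid-loaded cells, metallothioneins had a mean of 0.38 and a median of −0.10 (adjusted p = 0.170). With linalool against untreated cells, glycolysis and hypoxia genes had a mean of −0.02 and a median of 0.05 (0.733), and with fenofibrate metallothioneins had 0.15 and −0.05 (0.432).

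Across genes, the lipid-loaded arrays correlated with each other at r from 0.541 to 0.623, fenofibrate replicates 1 and 2 at 0.356 and the linalool replicates at 0.342. Fenofibrate replicate 3 correlated with the others at 0.0706 to 0.101 and had an array weight of 0.404. Groups of 3, 3 and 2 arrays were not tested for outliers.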
